A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

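Leaf RNA of 12 rice samples in 3 groups of 4 was extracted with Trizol and sequenced, per the labels' protocols. The authors deposited a table of whole-number counts per annotated gene and library, with 38978 rows and 1 column per library. The aligner, the counter, the genome build, the strandedness and any selection of messenger RNA are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical copies may have been split between rows. Samples were grouped by their titles, which give the genotype, the line and a replicate number from 1 to 4. Every column matched the description of 1 sample, and the totals ran from 14746933 to 19822636 counts. The labels describe more than a single season and site and assign none to a library, so no batch could be formed. Over all 66 pairs of libraries, the chi-square statistic of their counts divided by its degrees of freedom was 13.6 to 228, where repeated sequencing of the same library gives about 1. The lowest was WT replicate 4 with Line7 replicate 2.

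The rows comprised 37849 nuclear locus IDs, 1017 non-coding RNA IDs and 112 named organelle genes. The RefSeq gene table used (assembly ASM3414082v1) matched 1 of the nuclear and RNA IDs, and carries no product names. The 19 gene lists and 25 gene families that had been set before the data were examined (chlorophyll synthesis, light harvesting, photosystems, nitrogen assimilation, defence and others) therefore had 0 members that could be named, and were not tested. Under the rule for named genes, also set before the data were examined, a nuclear gene needed a product name, so none qualified. The rule put the microRNA's target first, then the genes with the largest changes that separated all libraries of the groups compared, then up to 4 called and up to 2 uncalled members of each list. Nuclear rows are given as counts and by at most 2 IDs that rose and 2 that fell, chosen after their values were seen apart from the target's ID. Organelle genes were assigned to the plastid or the mitochondrion where their symbol occurs in 1 organelle of the table (95 of 112). They were sorted into lists by symbol.

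Counts were analysed with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr on group (20217 rows), library sizes were scaled by TMM, and a quasi-likelihood model with robust estimation (glmQLFit and glmQLFTest) was fitted to all 12 libraries with group as the factor. Contrasts were Line7 against WT, Line8 against WT, the mean of both lines against WT, and Line8 against Line7. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and genes with an absolute log2 fold change of at least 1 were also counted. SEs were taken from the fold change and the F statistic. The common biological coefficient of variation was 32.2%. CPM values are counts scaled to a common library total after TMM (edgeR cpm). A count of 0 over a group was given a floor of 3 counts over the group, and intervals of ratios of summed counts are exact binomial at 95%. Both cover counting error only. A floor of 3 counts corresponds to 0.163 to 0.207 CPM in a single library. Lower bounds of folds use the TMM-scaled totals. Ratios of summed counts and their intervals use the library totals without TMM. For Os03g0426350, TMM-scaled totals gave ratios to WT of 525 in Line7 and 453 in Line8, and for Os10g0567900 a ratio of WT to Line8 of 221. Single values were compared with exact two-sided permutation tests. Lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry of the same package.

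On counts simulated from the real means, library sizes and dispersions of 20217 genes, with 200 genes changed, edgeR recovered 75.0% of the 4-fold and 23.0% of the 2-fold changes for Line7 against WT, 79.0% and 27.0% for Line8 against WT, 87.0% and 33.0% for the mean of both lines, and 72.0% and 14.0% for Line8 against Line7. Unchanged genes made up 3.1 to 5.08% of its calls. DESeq2, tested on the same simulated data, had 18.8 to 27.5% of its calls among unchanged genes. limma-voom had 1.92 to 5.13% of its calls among them, and recovered 71 to 88% of the 4-fold and 17 to 32% of the 2-fold changes. With sample weights, 1.92 to 5.22% of its calls were among unchanged genes. Overlap between lines was set beside 20 simulations of unchanged groups that share the WT libraries, and beside fits with the WT libraries divided. All simulations drew each gene independently, so they lack deviations that many genes of a library share. The real share of false calls may therefore be higher.

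Alternatives set before the data were examined were other size factors (RLE, upper quartile, library size only), 2 other filters, DESeq2 1.42.0, limma-voom, fits with only the libraries compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, 2 were added: leaving out Line7 replicate 2 and Line8 replicate 3 together, and limma-voom with estimated sample weights.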

Results

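RNA abundance was measured in leaves of field-grown rice (cultivar Nipponbare, a japonica variety) that were sampled at 10 in the morning. The 12 libraries formed 3 groups of 4 replicates. WT was the unmodified cultivar. Line7 and Line8 were transgenic lines 7 and 8 carrying an artificial microRNA, driven by the 35S promoter, against YGL1, the gene for chlorophyll synthase, which attaches the tail to chlorophyll in the last part of its synthesis. Line 1 of the same construct is named in the design and was not analysed here. The comparisons ask how leaf gene expression in the lines carrying this microRNA differs from WT and whether the lines respond alike. No group carried a control construct. Effects of the microRNA on its target therefore cannot be told apart from other effects of making or carrying the transgene. Library totals ran from 14746933 to 19822636 counts, and 20217 of 38978 annotated rows were abundant enough to test. Nothing in the labels says that replicates were separate plants, so p-values measure the spread between these samples. Nuclear rows carry only a locus ID that no table used here pairs with a name, so nuclear results are given as counts and by at most a few IDs, while genes of the organelles carry names.

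The locus ID written down as that of the microRNA's target before the data were examined was Os05g0349700. The files do not pair it with a name. Its normalised level was 54.7 ± 11.2 CPM (SD, n = 4) in WT, 39.4 ± 19.4 CPM in Line7 and 26.8 ± 4.54 CPM in Line8, each over 4 libraries. The WT libraries held 57.7, 44.2, 47.8 and 69.1 CPM. In Line7, replicates 1, 3 and 4 held 34.4, 27.4 and 27.8 CPM, whereas replicate 2 held 68.1 CPM, inside the WT range. The Line8 libraries held 26.1, 33.4, 23.8 and 24.0 CPM, all below every WT library. These levels rested on 398 to 1215 counts per library.

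In edgeR's quasi-likelihood test the log2 fold change of Os05g0349700 was -1.03 (SE 0.278, adjusted p = 0.0172) in Line8 and -0.47 (SE 0.275, adjusted p = 0.291) in Line7, against WT. The exact two-sided permutation test gave p = 0.0286 for Line8, the smallest value that 4 against 4 libraries allow, and p = 0.143 for Line7. For the mean of both lines the log2 fold change was -0.75 (SE 0.233, adjusted p = 0.0341), and 7 of 8 line libraries lay below every WT library. Without Line7 replicate 2 the Line7 change was -0.87 with an adjusted p of 0.00592. Without WT replicate 4 the adjusted p of Line8 was 0.0532. The call for the mean of both lines held without WT replicate 2, Line7 replicate 2 or Line8 replicate 2, and was lost without any of the remaining 9 libraries of the 3 groups (adjusted p from 0.0516 to 0.113). The lines themselves differed by -0.56 (SE 0.277, edgeR unadjusted p = 0.0651, adjusted p = 0.331, exact permutation p = 0.171), which did not pass the threshold. The unadjusted edgeR p was 0.00267 for Line8 and 0.00663 for the mean of both lines. Adjusted p-values cover all tested genes, so a lost call can also reflect the p-values of other genes.

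**Figure D1:**
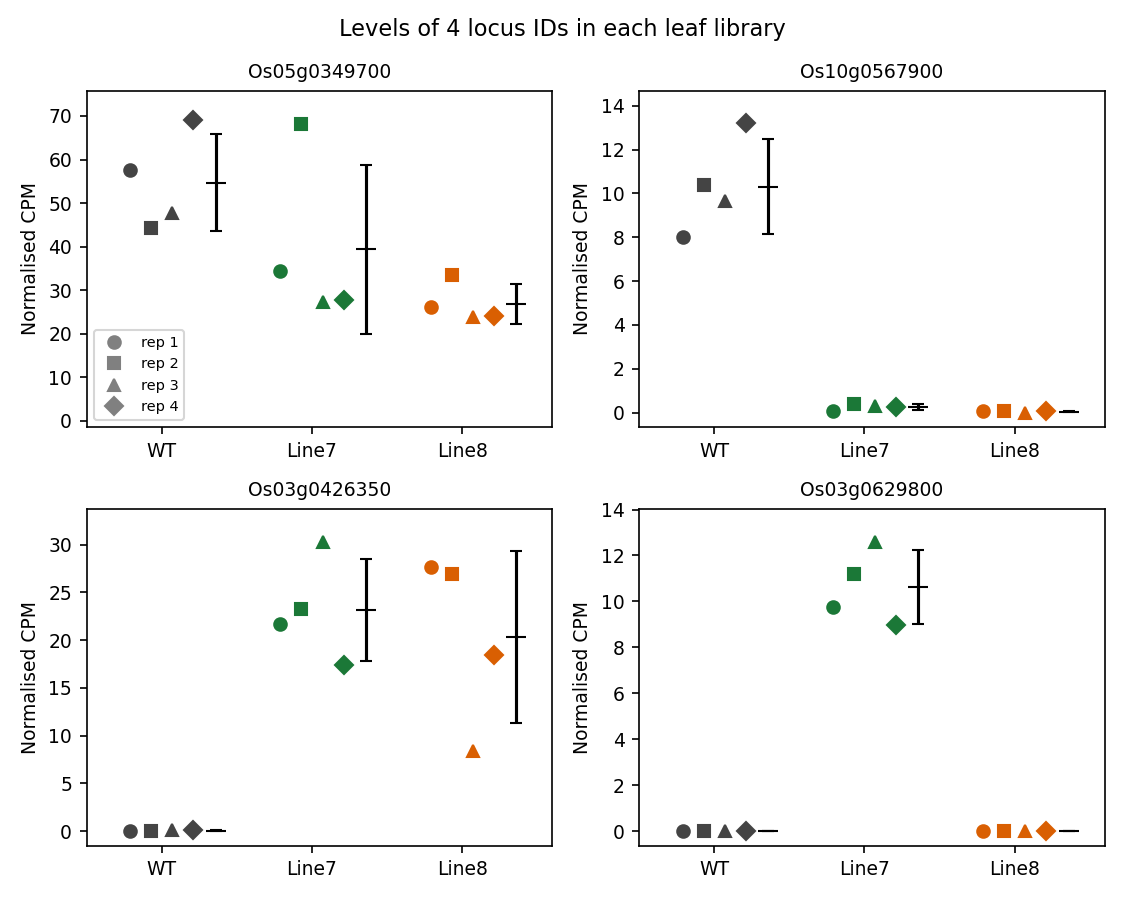
Normalised CPM (vertical axis) of 4 locus IDs in each library, with group on the horizontal axis, marker shape for the replicate, and a black bar for mean ± SD of 4 libraries. Os05g0349700 was at 68.1 CPM in Line7 replicate 2 against 27.4 to 34.4 CPM in the other Line7 libraries, and the remaining 3 IDs were chosen after their values were seen, among changes shared by all 4 Line7 libraries.

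The first principal component of log2 CPM, with 48.2% of the variance, separated WT from the lines except for Line7 replicate 2. That library scored -75.3, among the WT libraries at -85.2 to -62.1, whereas the other Line7 libraries scored 25.4 to 51.7 and the Line8 libraries 39.4 to 84.8. Its mean Spearman correlation, across genes, was 0.977 with WT libraries and 0.925 with the other Line7 libraries. The second component, with 22.2%, set WT replicate 1 (61.1) and Line8 replicate 3 (113) apart from the rest.

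**Figure D2:**
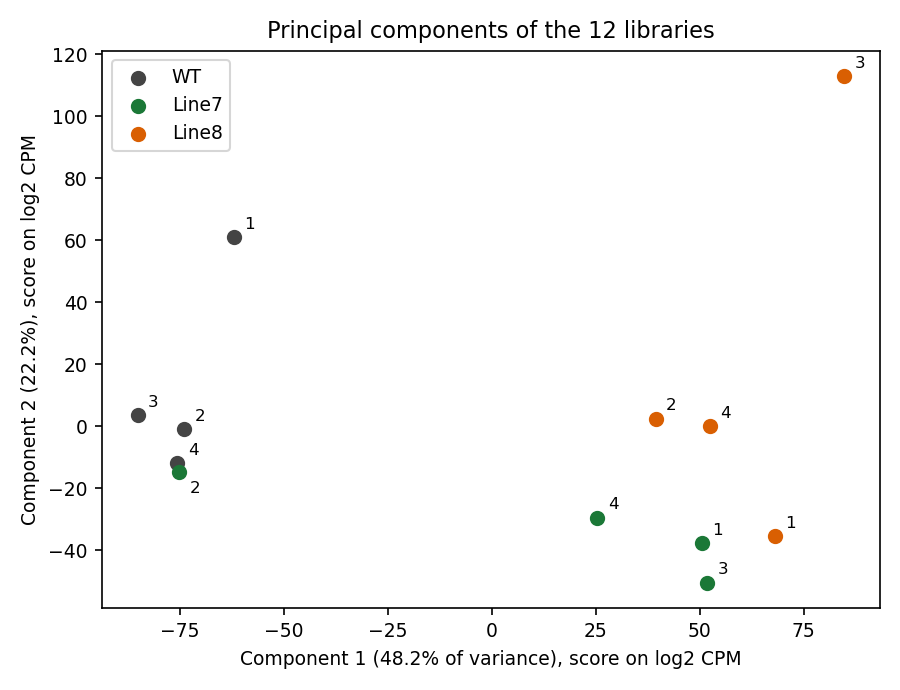
Scores of the 12 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, coloured by group and marked with the replicate number. Line7 replicate 2 lies at -75.3 on the first component with the WT libraries, and Line8 replicate 3 at 113 on the second.

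In Line7 against WT, 1196 genes rose and 213 fell (edgeR, Benjamini-Hochberg adjusted p below 0.05), of which 1032 and 86 changed at least 2-fold. Os03g0426350 was almost silent in WT, with 3 counts over the 4 libraries, and held 252 to 481 counts in each Line7 library. Its summed level was 546 times that of WT (95% counting interval 187 to 2650, log2 fold change 8.79, SE 0.613, adjusted p = 4.57e-05). Os03g0629800 had no count in any WT library and 130 to 200 counts in each Line7 library, at least 241-fold higher than the 3 counts over the group set as the floor for WT (adjusted p = 0.0015). Os10g0567900 fell from 10.3 ± 2.17 CPM (SD, n = 4) in WT to 0.262 ± 0.14 CPM in Line7, where 1 to 7 counts remained per library (log2 fold change -5.24, SE 0.418, adjusted p = 0.000107). These 3 IDs were chosen after their values were seen, among changes shared by all 4 Line7 libraries, so their level in replicate 2 does not stand for that of other genes. In replicate 2, where Os05g0349700 was at 68.1 CPM, Os03g0426350 was at 23.3, Os03g0629800 at 11.2 and Os10g0567900 at 0.392 CPM. The changes of these 3 IDs there thus went without a lower level of Os05g0349700. Whether they follow from the microRNA was not tested. Over all rows, 4 had at most 3 counts over the WT group and at least 10 in every Line7 library. When replicate 2 was not considered, 24 rows met that condition in the other 3 Line7 libraries.

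The number of genes called in Line7 depended on single libraries. Without Line7 replicate 2 it was 5156 (3058 higher and 2098 lower), among them all 1409 of the full set. It was 11, 490, 7 and 18 without WT replicates 1, 2, 3 and 4, and 14, 12 and 406 without Line7 replicates 1, 3 and 4. Without Line8 replicate 4, which is in neither group compared, it was 864. With 1 library of WT replicates 1 to 4, Line7 replicates 1, 3 and 4 and Line8 replicate 4 left out, 3 to 90 genes were lower in Line7, and without Line8 replicate 3 there were 390. DESeq2 called 3024 genes and limma-voom 22, and a fit with only the libraries compared called 587.

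**Figure D3:**
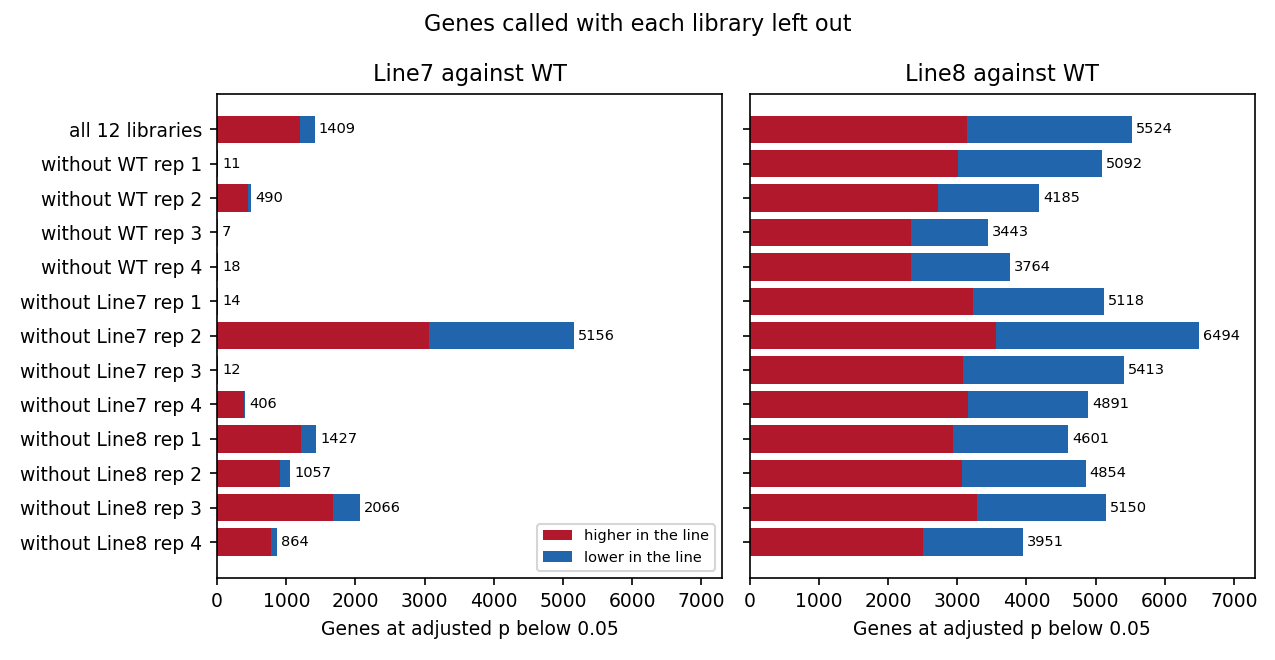
Number of genes called (horizontal axis, adjusted p below 0.05 in edgeR) for Line7 against WT (left) and Line8 against WT (right) with all 12 libraries and with each library left out in turn (vertical axis). Red counts genes higher in the line and blue genes lower. Line7 counts run from 7 to 5156 and Line8 counts from 3443 to 6494.

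In Line8 against WT, 3136 genes rose and 2388 fell, of which 2064 and 1296 changed at least 2-fold. Os03g0426350 again went from near silence to 142 to 464 counts per library, a summed level 451 times that of WT (95% counting interval 154 to 2190, log2 fold change 8.61, SE 0.613, adjusted p = 2.98e-05). Os10g0567900 fell to 3 counts over the 4 Line8 libraries against 694 in WT, a ratio of WT to Line8 of 222 (95% counting interval 75.8 to 1080). Os03g0629800 had no count in any Line8 library and was given the floor of 3 counts over the group. Rows with at most 3 counts over WT and at least 10 in every Line8 library numbered 17, and 4 rows showed the opposite. Without WT replicate 3 the number of calls fell to 3443, with 2333 higher and 1110 lower. Genes lower in Line8 numbered 1468 without WT replicate 2, 1432 without WT replicate 4 and 1440 without Line8 replicate 4. With upper-quartile scaling 46.3% of the called genes were higher, against 56.8% with TMM, and that scaling moved the median log2 fold change of all genes by -0.115.

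The mean of both lines against WT gave 2879 genes that rose and 2033 that fell, of which 1801 and 680 changed at least 2-fold. Without WT replicate 3 it gave 2309 genes, with 1675 higher and 634 lower (72.5% higher), and without WT replicate 4 it gave 3068, with 1986 higher and 1082 lower. The lower genes numbered 1277 and 1100 without WT replicates 1 and 2, 962, 1305 and 1021 without Line7 replicates 1, 3 and 4, and 3399 without Line7 replicate 2. With upper-quartile scaling 48.4% of the called genes were higher, against 58.6% with TMM. Os03g0426350 was higher in all 8 line libraries (log2 fold change 8.70, SE 0.596, adjusted p = 1.86e-05) and Os10g0567900 lower in all 8 (log2 fold change -6.41, SE 0.351, adjusted p = 1.97e-06).

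Genes called in both lines in the same direction numbered 1262, with 1106 higher and 156 lower, and 1 gene was called in opposite directions. Independent lists of these sizes would share 186 higher and 25.2 lower genes, and 20 simulations of unchanged groups against shared WT libraries shared 0. Groups without a change give few calls, so that 0 was nearly fixed in advance. It does not measure how many genes the shared WT libraries add between lines that both have calls. These simulations drew each gene independently and lack deviations that many genes of a library share. Their values may therefore lie below what library effects give. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at 0.828, against 0.501 in the simulations. Their covariance was 0.683, against 0.0737. With the WT libraries divided into separate pairs for each line, the covariance was 0.588 to 0.694 and 3 to 4 genes were shared, as Line7 then had 4 to 6 calls. Without Line7 replicate 2 the lines shared 4027 genes, and 2187 to 2431 with the WT libraries so divided. The shared number was 9, 455, 4 and 12 without WT replicates 1, 2, 3 and 4, and 11, 10 and 375 without Line7 replicates 1, 3 and 4. It was 757 without Line8 replicate 4.

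**Figure D4:**
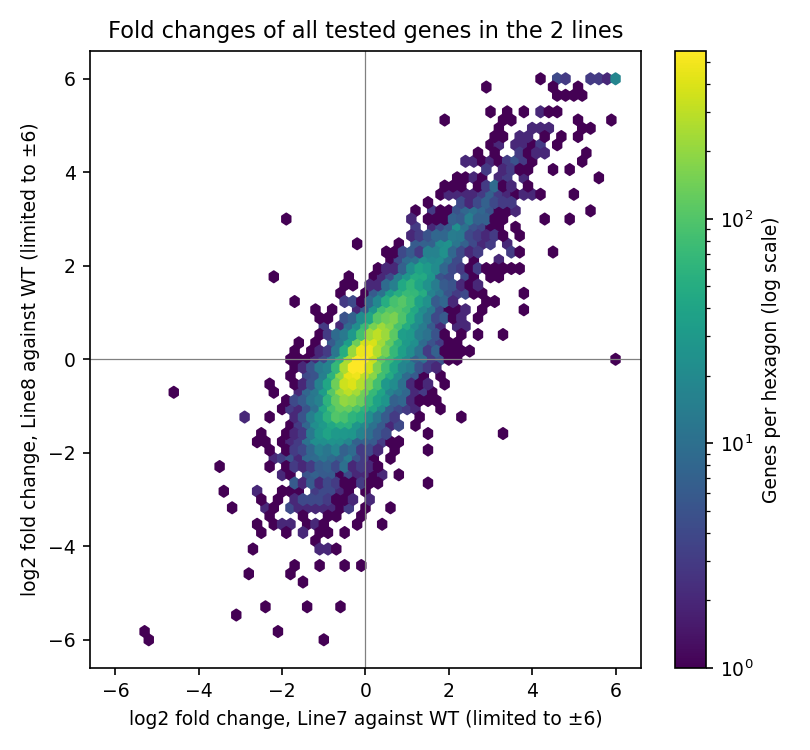
Log2 fold change against WT of each of 20217 tested genes in Line7 (horizontal axis) and Line8 (vertical axis), with values beyond 6 drawn at the edge and colour for the number of genes per hexagon on a log scale. The cloud lies along the diagonal (correlation 0.828, against 0.501 in simulations of unchanged groups with shared WT libraries and genes drawn independently).

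Line8 and Line7 differed in 5 genes, with 1 higher and 4 lower in Line8, whereas 3268 had an unadjusted p below 0.05. Os03g0629800 was the row with counts in all Line7 libraries (10.6 ± 1.59 CPM, SD, n = 4) and none in Line8, at least 231-fold higher in Line7 (adjusted p = 0.00472 in edgeR, and 0.0563 without Line7 replicate 1). It was the only row with at most 3 counts over Line8 and at least 10 in every Line7 library, and no row showed the opposite. DESeq2 called 474 genes and limma-voom 2. Leaving out single libraries gave 0 to 7 genes. The counts were 2, 3, 1 and 2 without WT replicates 1, 2, 3 and 4, 0, 1 and 3 without Line7 replicates 1, 3 and 4, and 3, 1, 1 and 1 without Line8 replicates 1, 2, 3 and 4.

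Organelle genes took a small part of the counts, with 0.0059 ± 0.000917% (SD, n = 4) in WT, 0.00728 ± 0.00255% in Line7 and 0.00867 ± 0.00404% in Line8. The share did not differ from WT past the threshold in either line (exact two-sided permutation test, p = 0.314 for Line7 and p = 0.257 for Line8). Line7 replicates 1, 3 and 4 held 0.00838, 0.00976 and 0.00717%, above the WT range of 0.00469 to 0.00689%. Line7 replicate 2 held 0.00381%, below that range. The Line8 libraries ran from 0.00481 to 0.0141%. Of 112 named organelle rows 23 could be tested. All organelle rows together held 647 counts in Line7 replicate 2, the lowest library, and 2218 in Line8 replicate 3, the highest. Any selection of messenger RNA is not given, so these counts may not measure the level of organelle RNA in the leaf. In Line8, 4 rose and 0 fell by edgeR, with 12 at an unadjusted p below 0.05. Over all 20217 tested genes edgeR called 27.3% in Line8, 6.97% in Line7 and 24.3% for the mean of both lines. The 4 of 23 in Line8 were thus no larger a share than among all genes. DESeq2 called 9 higher and 1 lower, and limma-voom 4 higher and 1 lower. By edgeR, 10 rose and 0 fell without Line7 replicate 2, 8 rose and 0 fell without Line8 replicate 2, 2 rose and 2 fell without Line8 replicate 3, and 1 rose and 0 fell without WT replicate 2. nad4L, for a subunit of mitochondrial complex I, rose from 0.837 ± 0.238 to 2.73 ± 1.43 CPM (SD, n = 4; log2 fold change 1.70, SE 0.496, adjusted p = 0.0236). ccmC, which acts in mitochondrial cytochrome c maturation, rose from 0.583 ± 0.242 to 1.72 ± 0.828 CPM (adjusted p = 0.0257). The mitochondrial open reading frame orf284 rose from 0.226 ± 0.179 to 1.40 ± 0.758 CPM (adjusted p = 0.0168). rps19-2, for a ribosomal protein, rose from 0.942 ± 0.364 to 4.03 ± 1.39 CPM (adjusted p = 0.0236). Its symbol occurs in both organelle genomes, so its counts could not be given to one of them, and it was named after its value was seen. These 4 genes had 1 to 22 counts in each WT library, so small shifts in counting weigh on them.

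**Figure D5:**
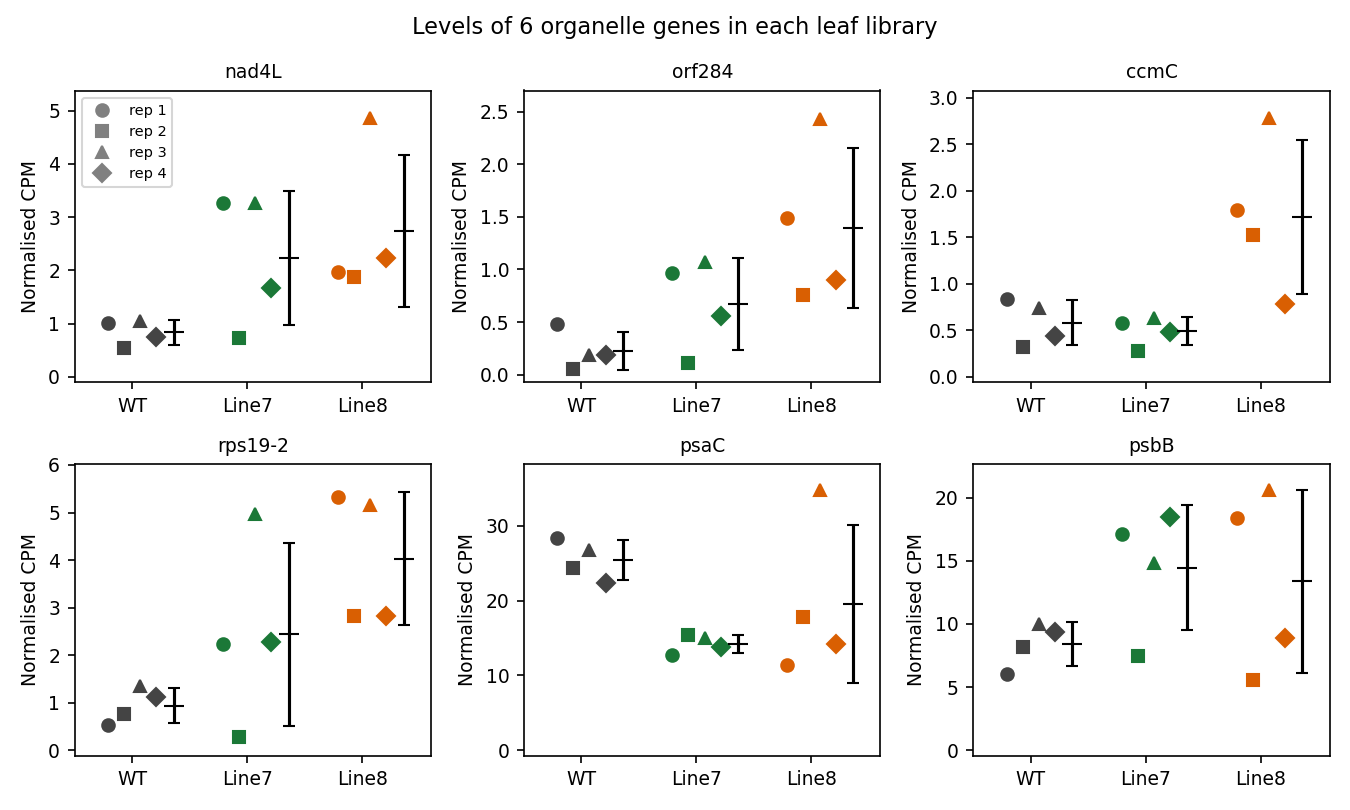
Normalised CPM (vertical axis) of 6 organelle genes in each library, by group (horizontal axis), with marker shape for the replicate and a black bar for mean ± SD of 4 libraries. In nad4L, orf284, ccmC, psaC and psbB, Line8 replicate 3 is the highest library, at 4.86, 2.43, 2.78, 34.8 and 20.6 CPM.

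The calls of nad4L and ccmC in Line8 were lost without WT replicate 2 (adjusted p = 0.0617 and 0.0685), without WT replicate 4 (0.0604 and 0.072) and without Line8 replicate 3 (0.0596 and 0.0615), by edgeR. The ccmC call was also lost in limma-voom with sample weights (log2 fold change 0.923, adjusted p = 0.0645). That of rps19-2 was lost without WT replicate 1 (0.0574), WT replicate 2 (0.059) or Line8 replicate 1 (0.0505). orf284 passed the threshold with each library left out. In Line7 edgeR called 0 of the 23 genes, with 5 at an unadjusted p below 0.05, DESeq2 called 1 higher and 1 lower, and limma-voom called 0. Without Line7 replicate 2, the library that lay with WT, edgeR called 5 of 24 organelle genes higher and 0 lower in Line7, with 14 at an unadjusted p below 0.05. nad4L was at 2.23 ± 1.26 CPM in Line7 (adjusted p = 0.0954, and 0.0132 without replicate 2). ccmC was at 0.493 ± 0.154 CPM in Line7. The difference between the lines did not pass the threshold in either gene by edgeR (adjusted p = 0.762 for nad4L and 0.202 for ccmC), while DESeq2 called ccmC (adjusted p = 0.0292). For the mean of both lines, 3 organelle genes rose, namely nad4L, orf284 and rps19-2 (adjusted p = 0.0262, 0.0353 and 0.0391), by edgeR. limma-voom called 0 of the 23, with 5 at an unadjusted p below 0.05, and DESeq2 called 5 higher. By edgeR, all 3 of these calls were lost without WT replicate 2, 3 or 4 (adjusted p from 0.0586 to 0.0993). Those of orf284 and rps19-2 were also lost without Line7 replicate 1 (0.0632 and 0.0597) or Line7 replicate 3 (0.067 and 0.0698). That of rps19-2 was further lost without WT replicate 1 (0.1), Line7 replicate 4 (0.0588) or Line8 replicate 1 (0.0595). Without Line7 replicate 2, 9 organelle genes rose and 0 fell for the mean of both lines. In that contrast 3 rose and 2 fell without Line8 replicate 3, and 11 rose and 2 fell with sample weights.

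By organelle list, the lists of organelle genes having been set after the files were opened but before any test value was seen, 13 mitochondrial genes were measured. In Line8, 3 of them rose and 0 fell (4 rose when adjusted over the list alone), with a median log2 fold change of 1.35. The list as a whole was higher than other genes by camera with a preset correlation of 0.01 (adjusted p = 0.0187), and not with an estimated correlation (adjusted p = 0.57 with an estimated correlation). The estimated correlation was 0.65, far above the preset 0.01, so camera p-values with the preset correlation are too small for this list. With the preset correlation 0 lists were called without WT replicate 2 or without Line8 replicate 3. In Line7, 0 of the 13 were called by edgeR, the median was 0.96, and camera gave an adjusted p of 0.217 for the list, and of 0.0248 without Line7 replicate 2, when 14 were measured (adjusted p = 0.562 with an estimated correlation). Between the lines, camera gave an adjusted p of 0.128 for this list, and it passed the threshold without Line7 replicate 3 (0.0125), Line8 replicate 2 (0.0189) or Line8 replicate 4 (0.0415). With an estimated correlation the adjusted p between the lines was 0.487, 0.628 and 0.658 in these 3 fits. Of the 13, the 3 open reading frames had a median of 1.41 in Line8 and the 3 cytochrome c maturation genes 1.35. By fry, the list of open reading frames was called in Line8 (adjusted p = 0.0385) and for the mean of both lines (0.0446), and not in Line7 (0.146). The list of all mitochondrial genes was not called by fry in Line8 (adjusted p = 0.161) or for the mean of both lines (0.286). Only 5 plastid genes were measured, and 0 were called in either line by edgeR.

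psaC, for an iron-sulphur protein of photosystem I, was the most abundant of the 23 organelle genes in WT, at 25.4 ± 2.68 CPM in WT and 14.2 ± 1.22 CPM in Line7 (SD, n = 4). All 4 Line7 libraries, replicate 2 included, lay below all 4 WT libraries (log2 fold change -0.84, SE 0.281, adjusted p = 0.0836 in edgeR over all genes, exact two-sided permutation p = 0.0286). It was past the threshold with DESeq2 (adjusted p = 0.0426), with only the libraries compared (0.0463), with sample weights (0.000756) and without Line8 replicate 3 (0.0176), where the alternatives ranged from 0.000756 to 0.129. In Line8 psaC was at 11.4, 17.8 and 14.2 CPM in replicates 1, 2 and 4 and at 34.8 CPM in replicate 3 (log2 fold change -0.38, adjusted p = 0.323, -0.77 with an adjusted p of 0.0101 without replicate 3, and -0.76 with an adjusted p of 0.00118 with sample weights). psbB, for a chlorophyll-binding protein of photosystem II, was at 8.40 ± 1.76 CPM in WT, 14.5 ± 4.93 CPM in Line7 (adjusted p = 0.214) and 13.4 ± 7.26 CPM in Line8 (adjusted p = 0.212), neither past the threshold by edgeR with all libraries.

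Among the 100 most abundant rows, ranked by their mean over all libraries, 9 rose and 16 fell in Line8, and 1 rose and 2 fell in Line7. Over all tested genes 27.3% were called in Line8 and 6.97% in Line7, so these rows were not called more often. These rows took 30.0 ± 1.71% of the counts in WT (SD, n = 4), 26.7 ± 1.95% in Line7 and 25.2 ± 4.44% in Line8. The share did not differ past the threshold in either line (exact two-sided permutation test, p = 0.0571 for Line7 and p = 0.0857 for Line8), and Line8 passed it without replicate 2 (exact p = 0.0286). For the 8 line libraries together against WT the exact p was 0.0424, and 0.0606 to 0.127 without any of WT replicates 2, 3 and 4, Line7 replicates 1 and 3 and Line8 replicates 1 and 4. Line8 replicate 3 was the lowest library at 19.8%, against 24.2 to 30.4% in the other Line8 libraries, and Line7 replicate 2 (28.8%) and Line8 replicate 2 (30.4%) lay inside the WT range of 28.1 to 31.9%.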

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

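The tests on Line7 replicate 2 and on the second principal component were chosen after those patterns were seen. In 46 sets of 4 replicates, 2 libraries stood apart from the other 3 of their group, by the gap to the nearest library over the range of the group, where chance gives about 2.3. nad4L was at 4.86 CPM in Line8 replicate 3 and at 1.87 to 2.23 CPM in the other Line8 libraries. Os10g0567900 was at 0 CPM in Line8 replicate 3 and at 0.0598 to 0.0691 CPM in the others, a difference of 1 count.

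The effects in the lines were compared directly by the contrast of Line8 with Line7, which called 5 genes. Among them Os03g0629800 had a fitted log2 fold change of -10.4, a value that depends on the prior count because no Line8 library held a count of it. Of the 35 splits of these 8 libraries, 1, the real one, called as many genes, and the highest other called 2. That is the fewest that 35 splits allow, so it argues against chance for the count with all libraries but cannot exclude it. The count itself rests on single libraries: it was 0 without Line7 replicate 1, 1 to 3 without any of the 10 libraries other than Line7 replicates 1 and 2, and 1 with only the libraries compared.

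Line7 replicate 2 lay near WT in the genes that changed: over 2452 genes called in both lines without it and at least 2-fold changed in Line7, it covered a median of 4.24% of the log2 distance from WT to the other Line7 libraries. The first test of a mislabelled WT library took 24 rows that were near 0 in WT and on in the other Line7 libraries, of which 4 had 10 or more counts in it, short of the majority asked for, a bound that wrongly took each row to mark the line whatever the state of the leaf. A second test, added after that, argues against a mislabelled WT library: 3 of the 24 rows lay at 101 to 182% of the Line7 level, and no row reached 50% in a left-out WT library, where the highest was 44.6%. The first test of a mixture of Line7 RNA with mostly WT RNA, the median of those rows at 6.13%, left it open, but a mixture gives every row a like percentage and is argued against by the same 3 rows at 101% or more beside 21 rows at 0 to 21.1%. What stays open is the hypothesis of a Line7 plant in which the target transcript was not lowered, with which 68.1 CPM of Os05g0349700 is consistent, but this is 1 library, and the level of that transcript could equally follow from another state of the leaf.

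WT replicate 1 and Line8 replicate 3 lay apart from the other libraries on the second component. Library size is argued against by their totals, 16.2 and 15.8 M (mega) counts, inside the range of the other libraries. A few genes taking most of the counts is argued against by the share of the 10 most abundant rows, which was 11.9% in WT replicate 1, inside the range of the other WT libraries, and 6.85% in Line8 replicate 3. Their deviations from their group means correlated at 0.55 across genes, the highest of 48 pairs of libraries from different groups, with the next at 0.46. The pair was picked for lying on the same side of that component, so this correlation largely follows from the choice and is no separate test. Shared handling and a shared leaf state could both set such a pair apart and cannot be told apart, because the labels give no batch, and no biological explanation was tested.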

How the results depend on the processing

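The alternatives with sample weights and with 2 libraries left out together were chosen after the data were seen. The cause of each change below was not tested. Leaving out a library also means fewer samples. That alone does not account for the rise of the Line7 count from 1409 to 5156 without Line7 replicate 2. Over the alternatives other than single left-out libraries, Line8 against WT gave 4826 to 9747 genes and the mean of both lines 4260 to 10365. Line7 against WT gave 22 with limma-voom, 587 with only the libraries compared, 3024 with DESeq2 and 8416 with sample weights. The shared count was 16 with limma-voom, 2448 with DESeq2 and 6445 with sample weights. Line8 against Line7 gave 1 with only the libraries compared, 2 with limma-voom, 474 with DESeq2 and 405 with sample weights. The highest counts for Line8 and for the mean of both lines, 9747 and 10365, came with sample weights. The weights were lowest for Line8 replicate 3 (0.206), Line7 replicate 2 (0.237) and WT replicate 1 (0.434), against 0.719 to 3.45 for the other libraries. With Line7 replicate 2 and Line8 replicate 3 both left out, Line7 gave 6684, the mean of both lines 8182, Line8 against Line7 11, and the shared count was 5047. Leaving out 1 library gave 7 to 5156 genes for Line7, 3443 to 6494 for Line8, 2309 to 7174 for the mean of both lines, 0 to 7 for Line8 against Line7, and 4 to 4027 shared genes.

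The target ID Os05g0349700 kept its direction in every alternative run, with a log2 fold change in Line7 of -0.70 with sample weights (adjusted p = 0.00679) and -0.84 with the 2 libraries left out (adjusted p = 0.00471), both past the threshold. Over the alternatives its adjusted p ran from 0.00471 to 0.394 in Line7, from 0.000654 to 0.019 in Line8 and from 0.000465 to 0.0434 for the mean of both lines. Leaving out 1 library gave -0.873 to -0.308 in Line7, -1.13 to -0.896 in Line8, -0.952 to -0.618 for the mean and -0.695 to -0.156 between the lines. Camera called 0 organelle lists in Line8 with an estimated correlation, against 1, and leaving out 1 library gave 0 to 1 lists in each contrast, the list of all mitochondrial genes each time. With an estimated correlation it called 0 lists in each of these fits (lowest adjusted p = 0.487 with an estimated correlation). Over the 4 contrasts Os05g0349700 kept its side of the threshold 78 times, gained the call 3 times and lost it 10 times. Of the values printed for the other named genes, under the alternatives and left-out libraries in which they were tested, 469 kept direction and side of the threshold, 15 gained the call, 31 lost it, and 5 reversed. These were psbB in Line8 with sample weights (-0.000224), and nad4L between the lines, which was not called in any of them, with sample weights (-0.112), with the 2 libraries left out (-0.417), without Line7 replicate 2 (-0.000714) and without Line8 replicate 3 (-0.114). Leaving out 1 library gave -0.114 to 0.543 for nad4L between the lines. psbB in Line7 gained the call with sample weights (adjusted p = 0.0166) and with the 2 libraries left out (adjusted p = 0.0282), against 0.0166 to 0.284 over its alternatives. Organelle genes called in Line7 numbered 10 in each of these 2 settings, with 9 higher and 1 lower. In Line8, 10 were higher and 2 lower with sample weights, and 7 higher and 2 lower with the 2 libraries left out. With only the libraries compared, 9 were higher and 0 lower in Line8. Genes at 1 to 22 counts per WT library are limited by depth.

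The replicate numbers did not pair the samples: deviations of libraries with the same number correlated at -0.39 to 0.33, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block, Line7 gave 475 genes, Line8 against Line7 gave 0, and the shared count was 426. Os03g0629800 between the lines then had an adjusted p of 0.159 (2.18e-16 to 0.159 over its alternatives), and camera called 1 list in Line7 and 1 for the mean of both lines, that of all mitochondrial genes (adjusted p = 0.0373 and 0.00446, and adjusted p = 0.687 and 0.412 with an estimated correlation). The block gave 6 called organelle genes in Line8 and 4 for the mean of both lines, against 4 and 3 by edgeR without it.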

Other observations

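Other splits of the libraries, a test set before the counts were seen, bear on each count of genes. For Line8 against WT, 1 of 35 splits, the real one, gave as many as 5524 genes and the highest other gave 0. That is the fewest that 35 splits allow, so it argues against chance but cannot exclude it. For Line7 against WT, 3 of 35 splits gave as many as 1409 genes, with 1965 in the highest other, so chance is not excluded for that count. In that split WT replicate 2 and Line7 replicate 2 changed places, and in the other, with 1891 genes, WT replicate 1 and Line7 replicate 2 did. Exchanging Line7 replicate 2 with WT replicate 4 or 3 gave 1108 or 436 genes, and every remaining split gave 0. The high counts in other splits thus point to the structure of the samples described for Line7 replicate 2. For the mean of both lines, 1 of 100 drawn splits gave as many as 4912 genes, and the highest other, 4611, had Line7 replicate 2 in place of WT replicate 2. For the genes shared by the lines, 1 of 100 drawn splits gave as many as 1262, and the highest other gave 4. Such splits break up both contrasts, so they do not measure what the shared WT libraries add to the shared number. For organelle lists in Line8, tested by camera with the preset correlation, 13 of 35 splits called as many as 1 list. The highest other called 4, so chance is not excluded.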
